A study of Mus musculus with 24 samples.

How the data were processed

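The series measured RNA in 2 mouse cell lines, C2C12 (myoblasts) and NSC34 (motor-neuron-like cells), grown without co-culture (control) or co-cultured with the other line for 3 days, per the labels and the series design. Each line had 6 control and 6 co-cultured libraries, 24 libraries in all. Total RNA was extracted with Trizol and sequenced on a Nanopore MinION after a standard library preparation, per the labels' protocols. The labels do not say how the lines were parted after co-culture, whether replicates were separate cultures, or whether a replicate number links libraries. The genome build is GRCm38, per the labels. The aligner, the counting program, the annotation release and any strand setting are not given in the sources used here.

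The values deposited by the authors are raw counts: whole numbers of reads per Ensembl transcript, with 1 column per library and 1 table per line, neither scaled nor logged. The columns were matched to samples by their names, and 0 columns were left unmatched. Transcript identifiers, without their version, were looked up in the GENCODE M21 annotation of GRCm38, from which gene symbols, gene positions and transcript types were taken. Of 37677 C2C12 transcripts 37415 matched, and of 10427 NSC34 transcripts 10374 matched. The deposited version numbers were the same as in that annotation for 13 transcripts of each table and 1 higher for 37048 and 10267 of them. The deposited annotation was therefore not the one used for names, and positions are those of GENCODE M21. Counts were summed over the transcripts of each gene, giving 15439 genes with reads in C2C12 and 7557 in NSC34.

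Depth ranged from 121154 to 658075 reads per C2C12 library and from 88 to 30314 per NSC34 library. For a gene with 0 reads the upper limit was taken as 3 reads of the total. Intervals of counts are exact Clopper-Pearson intervals at 95%. Such intervals and limits cover counting error only, since reads carry no molecular identifiers.

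Each line was tested by itself with edgeR 4.0.16 in R 4.3.3 (filterByExpr with the group, TMM scaling, quasi-likelihood F test, co-culture against control). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The filter left 2570 C2C12 genes, with 88.3% of the reads, and 49 NSC34 genes, with 28.2% of the reads. Levels of tested genes are given as CPM by the cpm function of edgeR, relative to the reads of tested genes and scaled by TMM. Levels of the genes fixed for their role at the synapse are also given as CPM of all reads, where so stated. The difference of the co-culture effect between the lines was an edgeR interaction test on the 49 genes tested in both.

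Before the data were examined, the tests, the filter, the alternatives and 22 gene lists were fixed. So was the rule for the genes named. It takes 12 genes of the synapse question, the 8 genes with the smallest p in each direction among those past the threshold (3 where none passed), the 3 largest changes with groups fully apart, up to 4 genes of smallest p per list, and the 5 smallest interaction p of each sign. A gene named outside that rule is said to be so. The lists were tested with camera in limma 3.58.1 on voom values, with a preset correlation of 0.01, where at least 5 members had been tested. List medians are of the limma-voom fold changes unless edgeR is named. The share of a library's reads taken by each list was compared with an exact two-sided permutation test over all 924 splits, for lists with at least 20 reads. That test was added after the filter had left 49 NSC34 genes, as was an interaction test on list totals.

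The alternatives fixed at that stage were RLE factors, library totals, DESeq2 1.42.0, limma-voom with sample quality weights, no filter, a mean count of at least 10, mitochondrial genes left out, shallow libraries left out, the replicate number as a block, each library left out in turn, and for lists an estimated correlation and fry. Added after seeing the data were a length and a GC correction (loess of span 0.5), repeat-like genes left out, 2 control libraries left out per line, and a filter of 10 reads in total for NSC34. Other groupings of the libraries were refitted for 100 splits, the real one included, with seed 1. Shared sequence between transcripts was searched with BLAST+ 2.17.0 in Python 3.11.15, at 100 or more bases and 90% identity or more. Genes with reads in C2C12 that share 100 or more bases with Gm10718 at 80% identity or more, 11 with itself, are called repeat-like, and Gm20594 was left out together with them.

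The edgeR fit was tested on simulated data, with the changed genes drawn from those tested in the real data. The recovery therefore applies to genes with enough reads to be tested, not to genes under the filter. At the C2C12 depth it recovered 33 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 52 of 66 changed 4-fold, and it called 7 of 2386 unchanged genes. At the NSC34 depth it recovered 0 of 4, 1 of 3 and 1 of 3 of such genes, of which 3, 2 and 1 had passed the filter. The simulated interaction recovered 8 of 8 genes changed 4-fold in C2C12 alone. It set less variation between libraries than NSC34 showed (edgeR dispersion 0.0795). Its genes were fixed as those tested in both lines, so none could be lost to the filter. It therefore does not measure the power of the real interaction test. No library was left out of the main tests.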

Results

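The libraries came from 2 mouse lines: C2C12, a myoblast line that forms muscle cells in culture, and NSC34, a motor-neuron-like line. Each line was grown without the other (control, n = 6) or with it for 3 days (co-culture, n = 6), and total RNA was read on a Nanopore MinION. The C2C12 control libraries 1 to 6 held 125872, 658075, 225344, 121154, 213184 and 153646 reads, and the co-cultured ones 351053, 547071, 143502, 151424, 351269 and 268041. The NSC34 control libraries 1 to 6 held 88, 4076, 4009, 2239, 4624 and 822 reads, and the co-cultured ones 4309, 30314, 5006, 3017, 9554 and 2807. Between 8528 and 12094 genes were detected per C2C12 library and between 69 and 5254 per NSC34 library. Over all 70865 NSC34 reads, a gene with no read may have made up to 42.3 CPM of all reads (74.0 CPM without co-culture 2, 189 CPM in controls alone), against 0.906 CPM over the 3309635 C2C12 reads. Mitochondrially encoded genes took 3.25 ± 0.225% of C2C12 control reads and 3.40 ± 0.438% of co-cultured reads (SD, n = 6).

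**Figure D1:**
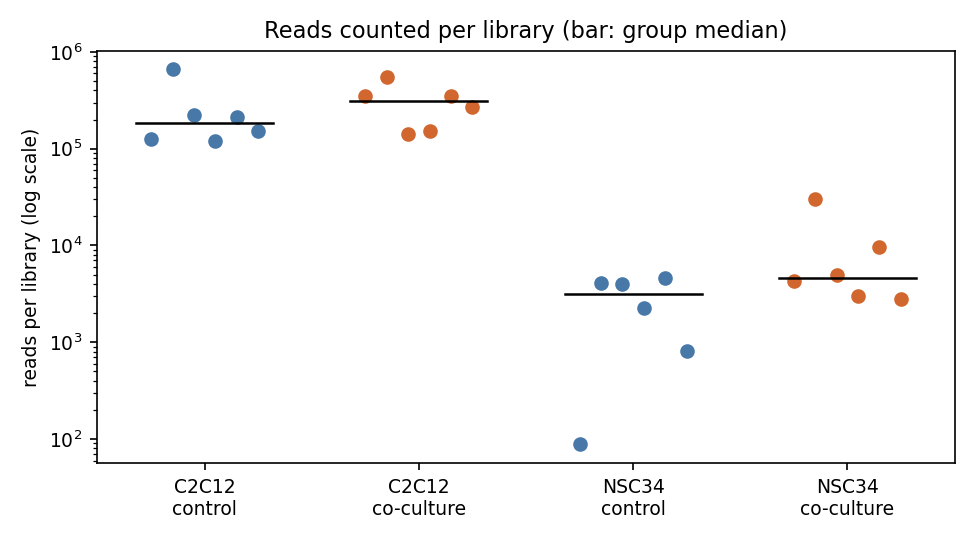
Reads counted per library (log axis) for the 4 groups of 6 libraries, with the group median as a bar. C2C12 libraries held 121154 to 658075 reads and NSC34 libraries 88 to 30314.

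The first comparison asked what 3 days with motor-neuron-like cells changed in C2C12 RNA. Contractile and sarcomere genes already took 4.66 ± 0.274% of C2C12 control reads (SD, n = 6). Several genes of differentiated muscle were higher in co-culture. Myoglobin (Mb, the oxygen-binding protein of muscle, chromosome 15, 77015487 to 77050670 in GRCm38) rose from 749 ± 63.0 to 1245 ± 82.7 CPM (SD, n = 6), a log2 fold change of 0.73 (SE 0.0808, edgeR adjusted p = 3.41e-05). Ckm, the muscle creatine kinase (chromosome 7, 19404776 to 19422841), rose from 375 ± 48.4 to 576 ± 55.9 CPM, a log2 fold change of 0.64 (SE 0.102, edgeR adjusted p = 0.00268). Cox8b, a cytochrome c oxidase subunit of heart and skeletal muscle (chromosome 7, 140898945 to 140900446), rose from 272 ± 52.7 to 455 ± 41.0 CPM, by 0.77 on the log2 scale (SE 0.117, edgeR adjusted p = 0.0023). In each of these 3 genes all 6 co-cultured libraries lay above all 6 controls. Tnnt1 (slow troponin T) and Tnni2 (fast troponin I) rose by 0.45 and 0.29 (edgeR adjusted p = 0.0139 and 0.0349). Atp2a1, the calcium pump of the sarcoplasmic reticulum, named here after its values were seen, rose by 0.66 (edgeR adjusted p = 0.0362). Of the 29 tested contractile and sarcomere genes these 5 (Mb, Ckm, Tnnt1, Tnni2, Atp2a1) rose, 0 fell and 24 did not pass. Adjusted over the list alone, 8 rose and 1 fell. The list as a whole rose, with a median log2 fold change of 0.11 (camera adjusted p = 5.56e-05, and 0.0325 with an estimated correlation). Of its 29 fold changes in edgeR, 20 were above 0 and 9 below. Its share of reads did not pass the exact test (adjusted p = 0.107).

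Among the 10 tested myogenic regulators and myoblast surface genes, Myog, the transcription factor that starts muscle differentiation, rose by 0.43 on the log2 scale (SE 0.106, edgeR adjusted p = 0.0457), from 2657 ± 381 to 3589 ± 558 CPM (SD, n = 6). Mef2a, another muscle transcription factor, fell by 1.22 (SE 0.296, edgeR adjusted p = 0.0415), from 101 ± 53.5 to 46.6 ± 7.08 CPM, and the remaining 8 did not pass. Des (desmin, the muscle intermediate filament) had a log2 fold change of 0.41 (edgeR adjusted p = 0.0952) and Mef2c one of -0.46 (edgeR adjusted p = 0.221). Adjusted over the list alone, 2 rose and 1 fell. The list did not pass (camera adjusted p = 0.359), and in edgeR its median of 0.23 and its mean of -0.0026 differed in sign.

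Genes of glycolysis and the response to low oxygen formed the list with the smallest p by camera with its preset correlation. With an estimated correlation, cholesterol synthesis and extracellular matrix had a smaller one (camera adjusted p = 0.0233 each). Tpi1 (triosephosphate isomerase, chromosome 6, 124810586 to 124814296) rose from 284 ± 51.4 to 448 ± 69.8 CPM, a log2 fold change of 0.64 (SE 0.125, n = 6, edgeR adjusted p = 0.0139). Gapdh, which follows it in glycolysis, rose from 4917 ± 469 to 6290 ± 597 CPM, by 0.35 (SE 0.0770, edgeR adjusted p = 0.0274). Of 11 tested members these 2 rose and 9 did not pass, among them Ldha (lactate dehydrogenase A, 0.45, edgeR adjusted p = 0.0524) and Pkm (pyruvate kinase, 0.32, edgeR adjusted p = 0.0952). Adjusted over the list alone, 9 rose and 0 fell. The list rose with a median log2 fold change of 0.38 (camera adjusted p = 4.01e-07; adjusted p = 0.0325 with an estimated correlation). Its share of all reads was 0.789 ± 0.0777% in controls and 1.02 ± 0.0807% in co-culture (SD, n = 6, exact p = 0.00216, the smallest that 924 splits can give; adjusted p = 0.0119 over 22 lists), and without control libraries 1 and 4 the difference of 0.189 percentage points had an exact p = 0.00952 and an adjusted p = 0.0524. Outside the list, Higd1a and Fam162a, mitochondrial proteins induced by low oxygen, rose by 0.72 and 0.64 (edgeR adjusted p = 0.0064 and 0.0115), and Mif, a cytokine, rose by 0.45 (edgeR adjusted p = 0.0115).

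Among the remaining higher genes, Lgals3 (galectin-3, a sugar-binding protein, chromosome 14, 47367751 to 47386160) rose from 197 ± 42.8 to 405 ± 103 CPM, a log2 fold change of 1.0 (SE 0.168, n = 6, edgeR adjusted p = 0.00488). Spp1 (osteopontin, a secreted matrix protein) rose by 0.48 (edgeR adjusted p = 0.00981) and Dhrs3, a retinaldehyde reductase, by 1.10 (edgeR adjusted p = 0.0335), each with all 6 co-cultured libraries above all controls.

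Respiratory chain and ribosomal protein genes moved little one by one. None of 23 nuclear-encoded respiratory genes passed (0 rose, 0 fell), with Cox5b at 0.35 (edgeR adjusted p = 0.0545). Adjusted over the list alone 1 rose, and the list median was 0.12 (camera adjusted p = 0.00274; adjusted p = 0.267 with an estimated correlation). None of 58 cytosolic ribosomal protein genes passed, also over the list alone (0 genes), with Rpl35 at 0.17 (edgeR adjusted p = 0.256). That list had a median of 0.07 (camera adjusted p = 0.00119; adjusted p = 0.289 with an estimated correlation). With a transcript-length trend removed per library, an alternative added after seeing the data, neither passed with camera (adjusted p = 0.0768 for the respiratory chain and 0.788 for ribosomal proteins). The ribosomal list did not pass without control 2 either (camera adjusted p = 0.0509). Of 12 mitochondrially encoded genes 0 passed, with mt-Nd1 at 0.22 (edgeR adjusted p = 0.176), and the list did not pass (camera adjusted p = 0.686). It passed higher in 1 of 8 other settings, with the GC trend removed, added after seeing the data (median 0.22, camera adjusted p = 0.000605).

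Cholesterol synthesis and matrix genes were lower in co-cultured C2C12. Hmgcs1, which makes the precursor of mevalonate (chromosome 13, 119690379 to 119708260), fell from 144 ± 43.3 to 68.2 ± 15.8 CPM, a log2 fold change of -1.04 (SE 0.215, n = 6, edgeR adjusted p = 0.0167). It was the 1 of 11 tested cholesterol genes to pass, and 0 rose. Fdps (-0.54) and Idi1 (-0.64), enzymes of the same pathway, had edgeR adjusted p = 0.0587 and 0.0758, and adjusted over the list alone 6 fell. All 11 fold changes were below 0, and the list fell, with a median of -0.50 (camera adjusted p = 5.29e-06; adjusted p = 0.0233 with an estimated correlation). Its share of reads was 0.186 ± 0.0137% in controls and 0.134 ± 0.0111% in co-culture (n = 6, exact p = 0.00216, adjusted p = 0.0119). Of 19 tested extracellular matrix genes, Col1a2 (a chain of type I collagen) fell by 0.56 (edgeR adjusted p = 0.0365) and 18 did not pass, among them Fn1 (fibronectin, -0.53) and Sparc (-0.29), both with edgeR adjusted p = 0.0524. Adjusted over the list alone 7 fell. The matrix list fell, with a median of -0.16 (camera adjusted p = 1.61e-05; adjusted p = 0.0233 with an estimated correlation). Its share was 0.951 ± 0.0711% and 0.809 ± 0.0329% (n = 6, exact p = 0.00216, adjusted p = 0.0119).

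Of 9 tested cell cycle genes, Top2a, the topoisomerase of dividing cells, fell by 1.18 on the log2 scale (edgeR adjusted p = 0.0457), also as the 1 gene adjusted over the list alone, and 8 did not pass. Rrm2 (-0.44) and Mcm4 (-0.44), of DNA replication, had edgeR adjusted p = 0.331 and 0.413. The camera test of this list did not pass (adjusted p = 0.0734; adjusted p = 0.154 with an estimated correlation). The list passed lower in 3 of 8 other settings (limma adjusted p = 0.0288 with fry, 0.0192 with the replicate block and 0.0421 with a mean count of at least 10). It also passed in 5 of 12 cases with 1 library left out: control 1 (camera adjusted p = 0.038), control 3 (0.00823) and co-culture 3, 5 and 6 (0.041, 0.0137 and 0.0489). The share of all reads on its 36 members fell from 0.121 ± 0.00695% to 0.0952 ± 0.00611% (n = 6, exact p = 0.00216, adjusted p = 0.0119). Nes (nestin, an intermediate filament of precursor cells) fell by 0.82 (edgeR adjusted p = 0.0139) and Sox11, a transcription factor of progenitors, by 0.82 (edgeR adjusted p = 0.0347). Fstl1, a secreted glycoprotein, fell by 0.64 and Actb, cytoplasmic actin, by 0.50 (edgeR adjusted p = 0.0139 and 0.0145). Ahnak, a large scaffold protein, fell by 0.65 (edgeR adjusted p = 0.0349). The splicing factors Srsf3 and Sf3b2 fell by 0.46 and 0.73 (edgeR adjusted p = 0.0335 and 0.0347). All 6 co-cultured libraries lay below the control median for each of these genes (Nes, Sox11, Fstl1, Actb, Ahnak, Srsf3, Sf3b2).

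The series title concerns Apoe3, Lrp4 and acetylcholine receptor clustering, so the genes of that apparatus were listed whatever their result. Lrp4, the agrin receptor (chromosome 2, 91457511 to 91513779), was at 659 ± 114 CPM in controls and 691 ± 99.3 in co-culture (SD, n = 6), a log2 fold change of 0.12 (95% interval -0.14 to 0.37, edgeR adjusted p = 0.784). The receptor subunit Chrna1 was at 808 ± 48.0 and 873 ± 57.7 CPM, a log2 fold change of 0.11 (95% interval -0.05 to 0.26, edgeR adjusted p = 0.607). The other subunits had log2 fold changes of 0.24 (Chrnb1), 0.40 (Chrnd) and 0.29 (Chrng), with edgeR adjusted p = 0.722, 0.416 and 0.511. Rapsn, the scaffold that anchors the receptor, and Dok7, the activator of MuSK, had -0.03 and 0.05 (edgeR adjusted p = 0.986 and 0.957). Leaving out control library 2, the deepest, turned Lrp4 to -0.02, Dok7 to -0.06 and Rapsn to 0.02. Musk, the kinase, had 74 reads in controls and 77 in co-culture and was under the filter, as was Apoe. Apoe (apolipoprotein E) had 23 of 1497275 control reads (15.4 CPM of all reads, interval 9.74 to 23.0) and 45 of 1812360 co-cultured reads (24.8 CPM of all reads, interval 18.1 to 33.2). Without the filter its log2 fold change was 0.74 (SE 0.413, edgeR adjusted p = 0.611). Agrn (agrin) had 1 and 4 reads, Ache (acetylcholinesterase) 0 and 2, and Chrne (the adult subunit) 0, which allows up to 0.906 CPM of all reads.

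Of the 11 tested members of the receptor and agrin-LRP4-MuSK list, 1 fell (Nes), 0 rose and 10 did not pass, the same over the list alone (1 lower, adjusted over the list alone). The list did not pass (camera adjusted p = 0.34; adjusted p = 0.526 with an estimated correlation). Of 5 tested apolipoprotein and LDL receptor genes 0 passed, with Lrp1 at -0.51 (edgeR adjusted p = 0.18) and Lpl at 0.51 (edgeR adjusted p = 0.275), and the list had camera adjusted p = 0.977. Nor did 3 further lists pass: heat shock proteins (camera adjusted p = 0.226; Hsp90ab1 -0.39, edgeR adjusted p = 0.0524), the amino-acid and ER stress response (0.17; Hsp90b1 -0.42, 0.0747) and p53 targets (0.359; Cdkn1a -0.41, 0.127). Adjusted over the list alone, 2 heat shock genes, 1 stress gene and 1 p53 target fell.

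Markers of other cell types and the smaller lists were compared by their share of C2C12 reads. Neuronal and presynaptic genes took 0.0345 ± 0.00332% of control reads and 0.0308 ± 0.00507% of co-cultured reads (n = 6, exact p = 0.171, adjusted p = 0.269). Motor neuron and cholinergic genes took 0.00289% and 0.0036% (adjusted p = 0.568), and glial and Schwann cell markers 0.012% and 0.0111% (adjusted p = 0.378), by the exact test. Adipocyte markers took 0.00915% and 0.0129% (exact p = 0.039, adjusted p = 0.107) and interferon response genes 0.103% and 0.114% (exact p = 0.0476, adjusted p = 0.116). Neurotrophic factors (adjusted p = 0.585), immediate early genes (0.594) and the Notch pathway (0.881) did not pass the exact test either. Muscle contractile genes took 4.66% and 5.04% (adjusted p = 0.107) and myogenic regulators 0.482% and 0.584% (adjusted p = 0.0571). Of all 22 lists, 4 had a changed share: glycolysis and hypoxia higher, and cholesterol synthesis, extracellular matrix and cell cycle lower. With the 10 most counted genes left out of the total, myogenic regulators also passed higher (difference 0.114 percentage points, exact test, adjusted p = 0.0476). With 1 library left out 1 more list passed the exact test in 5 cases: contractile genes without control 2 (adjusted p = 0.0476), heat shock proteins without control 4 (0.0476), p53 targets without control 6 (0.00952), and myogenic regulators without co-culture 1 (0.0476) or 2 (0.0119).

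Over all 2570 tested C2C12 genes, 37 passed in edgeR, 21 higher and 16 lower, and 378 had an unadjusted p under 0.05. The groups were fully apart in 39 genes (1.52%, against 0.216% by chance), of which 20 had passed. Among the 37 were Gm10718, a repeat-like gene model that shares sequence with 12 other annotated genes at 90% identity or more, and Gm20594, 88.4% identical to mitochondrial Rnr2 over 439 bases, so their reads are uncertain. Fold changes also went with transcript length: across 2560 genes, which are not independent replicates, Spearman's rho of the log2 fold change with transcript length was -0.28. The median log2 fold change was 0.07 in the 512 genes with the shortest transcripts and -0.15 in the 512 with the longest. The genes past the threshold followed this trend. From the shortest to the longest of 5 bins of 512 genes, 9, 7, 2, 2 and 1 passed higher. In the same order 2, 1, 1, 5 and 7 passed lower. With the length trend removed per library, 24 of the 37 still passed and all 37 kept their direction. The number of genes passing rested on single libraries: it was 10 without control libraries 1 and 4, 11 without control 3, 12 without co-culture 2, 18 without control 1, 19 without co-culture 5, 22 without co-culture 1, 24 without co-culture 3, 73 without control 6 and 74 without control 5. Mb, Cox8b, Ckm, Higd1a, Lgals3 and Spp1 passed in all 12 other settings and with each of the 12 libraries left out in turn. With 1 library left out, Fam162a, Mif and Tpi1 also passed in 12 of 12 cases, Fstl1 and Tnnt1 in 11, Nes, Hmgcs1 and Actb in 10, and Dhrs3 and Gapdh in 8. Sf3b2 passed in 6, Ahnak, Col1a2 and Atp2a1 in 5, Myog, Srsf3, Sox11 and Tnni2 in 4, and Mef2a and Top2a in 3. Over the 12 other settings, Actb, Fam162a, Fstl1, Mif, Nes, Tnnt1 and Tpi1 passed in 11, Atp2a1, Gapdh and Hmgcs1 in 10, Ahnak, Col1a2, Dhrs3 and Sf3b2 in 9, Myog, Srsf3 and Tnni2 in 8, and Mef2a, Sox11 and Top2a in 7. In 1 of these settings, DESeq2, no adjusted p was given for Dhrs3, Hmgcs1, Mef2a, Sox11 and Top2a. The largest adjusted p, by any of edgeR, DESeq2 and limma, was 0.396 for Srsf3, 0.168 for Myog and 0.164 for Mef2a.

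**Figure D2:**
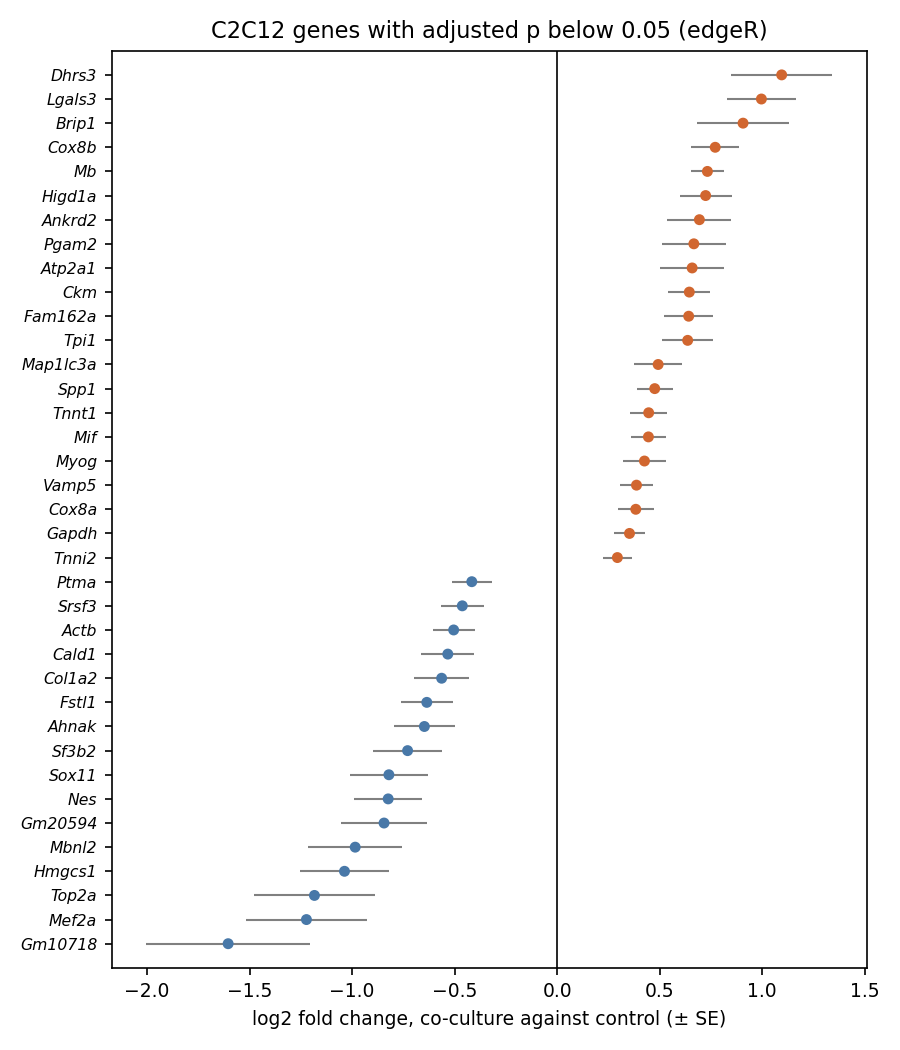
Log2 fold change (x axis, co-culture against control, with the standard error as a bar) of the 37 C2C12 genes past the edgeR threshold, 6 libraries per group. The 21 higher genes lie between 0.29 and 1.10 and the 16 lower genes reach -1.60 in Gm10718.

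**Figure D3:**
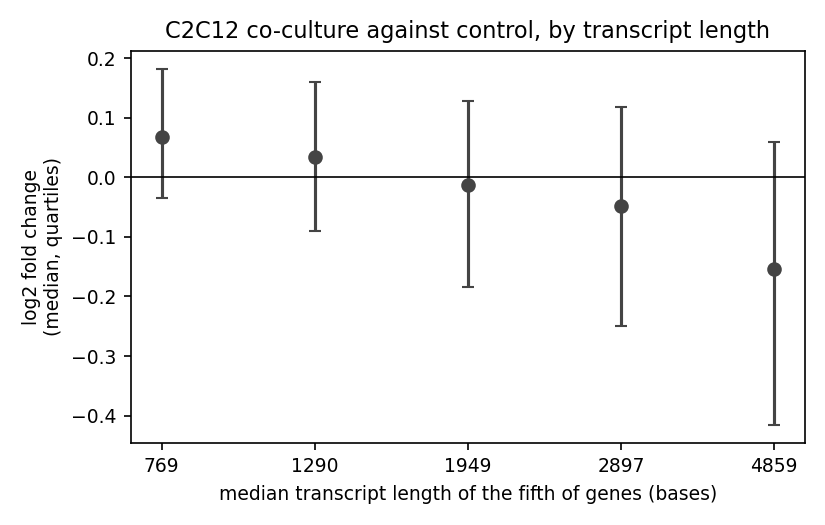
Median log2 fold change (y axis, quartiles as bars) of C2C12 genes in 5 bins of 512 genes by transcript length in bases (x axis). The median goes from 0.07 in the bin of the shortest transcripts to -0.15 in that of the longest.

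The second comparison asked what co-culture with C2C12 changed in NSC34 RNA, at a far lower depth. As a group, genes of glycolysis and low oxygen took 0.347 ± 0.257% of reads in the 6 NSC34 controls and 1.03 ± 0.176% in the 6 co-cultured libraries (SD, exact p = 0.00216, the smallest that 924 splits can give; adjusted p = 0.0281 over 13 lists). All co-cultured libraries (0.816 to 1.26%) lay above all controls (0 to 0.714%). Pooled, the list had 78 of 15858 control reads (0.492%) and 616 of 55007 co-cultured reads (1.12%). Gapdh had 22 and 175 reads, a ratio of 2.29 per read (interval 1.47 to 3.75), and Pkm, pyruvate kinase, 12 and 125, a ratio of 3.00 (interval 1.66 to 5.97). Ldha, lactate dehydrogenase A, had 8 and 72 reads, a ratio of 2.59 (interval 1.25 to 6.24). Aldoa had a ratio of 2.14 (interval 1.17 to 4.29), while the intervals of Tpi1 (2.59, 0.621 to 23.1), Eno1 (1.24, 0.532 to 3.33) and Pgk1 (1.73, 0.385 to 15.9) included 1. All these intervals pool reads over libraries and cover counting error only, not variation between libraries. Co-culture 2 gave 30314 of the 55007 co-cultured reads. None of these 7 genes passed edgeR with a filter of 10 reads in total, with adjusted p = 0.0691 for Pkm, 0.197 for Gapdh and 0.271 for Ldha. Another member, Bnip3, did pass with that filter (edgeR adjusted p = 0.0416) and is described below. Without controls 1 and 6 the difference went from 0.684 to 0.541 percentage points (exact p = 0.00476, adjusted p = 0.0619). That exact p is the smallest these libraries can give, so 1 list alone could not pass over 13 lists. Without any 1 co-cultured library it was 0.638 to 0.727 points (exact p = 0.00433, adjusted p = 0.0563).

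Low-oxygen genes outside the filter were looked at after their values had been seen. Bnip3, a mitophagy receptor, had 0 control reads and 32 in co-culture, and Higd1a 0 and 37, each in all 6 co-cultured libraries. Fam162a had 0 and 30, in 5 co-cultured libraries. Bnip3 is a member of the glycolysis and hypoxia list, so its reads are already part of the share above. In C2C12 the log2 fold change of Bnip3 was 0.65 (edgeR adjusted p = 0.196). Against 3 reads over the NSC34 control group, Bnip3, Higd1a and Fam162a were 3.08-fold, 3.56-fold and 2.88-fold higher. With the counting error of both groups the lower 95% limits of the ratios were 2.36, 2.75 and 2.20. Mif had 16 and 165 reads, a ratio of 2.97 (interval 1.78 to 5.32). With a filter of 10 reads in total, added after seeing the data, Higd1a, Bnip3, Fam162a, Mif and the gene model Gm7336 passed higher and Kif24 and Gm10719 passed lower in edgeR (7 genes, adjusted p = 0.04 to 0.0462). Without control library 1, of 88 reads, 6 genes passed: Fam162a (edgeR adjusted p = 0.073) and Gm7336 no longer did, and Gm10800 passed lower (edgeR adjusted p = 0.0241). That filter moved the fold changes of the 49 genes also tested in the main analysis upward, toward co-culture, by a median of 0.28. The median log2 fold change of all genes it tested was 0.37. The genes that passed higher with it did so on that shifted scale.

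**Figure D4:**
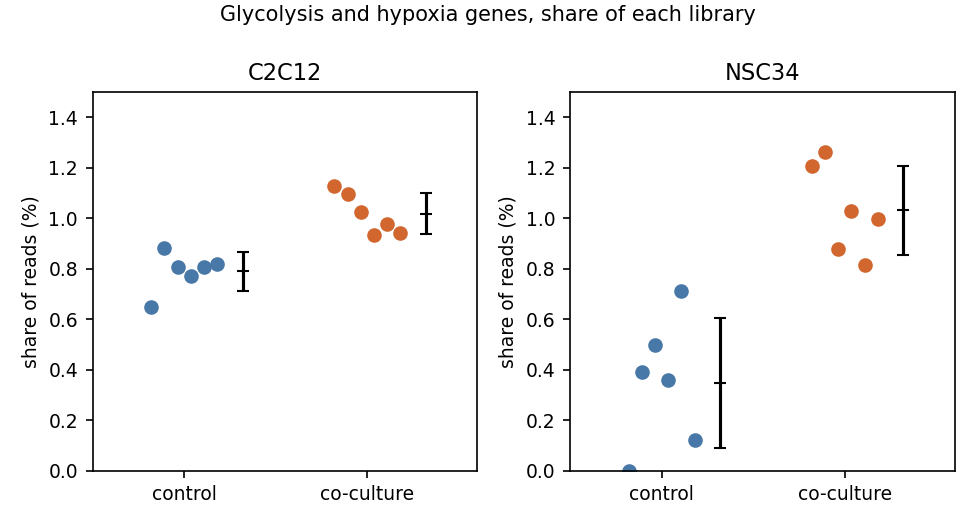
Share of each library's reads (percent, y axis) on genes of glycolysis and hypoxia, per library, with mean and SD beside each group of 6. C2C12 went from 0.789 to 1.02% and NSC34 from 0.347 to 1.03%.

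With the planned filter 49 NSC34 genes were tested with edgeR and 0 passed, with 1 gene at an unadjusted p under 0.05. DESeq2 and limma-voom with quality weights also passed 0, with 1 and 4 genes at an unadjusted p under 0.05. That gene was S100a6, a calcium-binding protein, with 67 control and 128 co-cultured reads and a log2 fold change of -0.87 (SE 0.294, edgeR adjusted p = 0.254), below the control median in all 6 co-cultured libraries. Next below came Rps23 (-0.57) and Eef1a1 (-0.50), a ribosomal protein and the elongation factor that carries transfer RNA to it, both with edgeR adjusted p = 0.842. Next above came Ndufa4 (0.64, a mitochondrial respiratory protein, edgeR adjusted p = 0.842) and the ribosomal genes Rps26 and Rpl31 (0.51 and 0.47, both 0.925). The simulation changed genes drawn from those tested in the real data. Of 3 changed 4-fold at this depth, 1 still passed the filter and was recovered. Of those changed 1.5-fold and 2-fold, 0 of 3 and 1 of 2 genes past the filter were recovered. Leaving out 1 library passed 1 gene in 3 cases: Apobec3 lower without control 3 and without co-culture 2, and Mif higher without control 5.

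Of the 22 lists, 2 had enough tested NSC34 genes for camera, and 0 passed: mitochondrially encoded genes (5 tested, mt-Nd1 -0.35, mt-Nd2 -0.41, mt-Nd4 -0.38 and mt-Cytb 0.16) and ribosomal proteins (19 tested), each with adjusted p = 0.617. For ribosomal proteins the median of 0.06 and camera's direction, down, differed in sign. By share of reads, 13 lists had 20 or more reads and 1 passed, glycolysis and hypoxia. The respiratory chain took 1.23 ± 0.63% and 1.90 ± 0.222% (exact p = 0.00866, adjusted p = 0.0563) and cell cycle genes 0.296 ± 0.178% and 0.535 ± 0.169% (exact p = 0.0303, adjusted p = 0.131), n = 6. Without control 1, of 88 reads and with a respiratory share of 0%, the respiratory difference went from 0.675 to 0.429 percentage points (exact p = 0.0152, adjusted p = 0.0985). The respiratory chain passed without control 2 or control 5 (differences 0.778 and 0.754 points, both exact p = 0.00649, adjusted p = 0.0422). The other 10 had adjusted p of 0.626 or more by the exact test: ER stress (0.626), the receptor apparatus, cholesterol synthesis, motor neuron genes and mitochondrially encoded genes (each 0.682), apolipoproteins, the interferon response and ribosomal proteins (each 0.691), neuronal genes (0.783) and heat shock proteins (0.976). Muscle contractile genes had 3 control and 10 co-cultured reads, myogenic regulators 2 and 11, and matrix genes 4 and 5, too few for the test. So had neurotrophic factors (3 and 12), immediate early genes (6 and 12), p53 targets (1 and 12), the Notch pathway (1 and 3), adipocyte markers (0 and 1) and glial markers (0 and 7).

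Of the synapse genes, Chrna1 had 3 control and 17 co-cultured NSC34 reads and Ache 1 and 0. Apoe, Lrp4, Musk, Agrn, Rapsn, Dok7, Chrnb1, Chrnd, Chrne and Chrng had 0 reads in NSC34, which allows up to 42.3 CPM of all reads (189 in controls and 54.5 in co-culture). Several of the most counted NSC34 features are uncertain: the transcript that held nearly all Elp6 reads shares sequence with 867 other genes, and the one behind Noct is 97.6% identical to Gm42860 over 3984 bases.

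The third comparison asked whether the co-culture effect differed between the lines. Of 49 genes tested in both, 0 differed in edgeR, 4 had an unadjusted p under 0.05, and DESeq2 passed 2, S100a6 (-0.84) and Rps23 (-0.60, NSC34 effect minus C2C12 effect). The smallest edgeR adjusted p was that of S100a6 (difference -0.86, SE 0.300, adjusted p = 0.412). On its side followed, in order of p, Rps23 (-0.60), mt-Nd1 (-0.61), Cox8a (-0.47) and Eef1a1 (-0.47). Of the opposite sign were Rpl31 (0.55), Ndufa4 (0.57), Rps26 (0.54), Ppia (0.30) and Rps29 (0.41), all with edgeR adjusted p between 0.524 and 0.579. Cell cycle genes differed as a list total, in a test added after seeing the data: their log2 change was -0.33 in C2C12 and 0.67 in NSC34, a difference of 1.0 (SE 0.215, edgeR adjusted p = 0.000594 over 13 lists; exact permutation adjusted p = 0.00161). For glycolysis and hypoxia the log2 changes were 0.36 and 1.13, a difference of 0.77 (SE 0.222, edgeR adjusted p = 0.00944). The exact permutation test of that difference did not pass (adjusted p = 0.355), nor did edgeR without NSC34 co-culture 2 (difference 0.60, adjusted p = 0.0739). The other 11 list totals did not differ, with edgeR adjusted p of 0.293 or more.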

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

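The splits of the libraries and, for the repeat-like genes, the intron and depth comparisons were set before their results were seen, and all other tests of explanations in this part, as well as the list totals, were chosen after.

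Among 100 splits of the C2C12 libraries into 2 groups of 6, the real one included, 1 gave as many genes as the real 37. The highest other split gave 19. Chance is therefore an unlikely source of that count, but 100 splits cannot exclude it. For the 6 C2C12 lists chance cannot be excluded: 10 of 100 splits gave as many, and the highest other gave 8. For the 0 NSC34 genes, the 0 NSC34 lists and the 0 genes that differed between the lines, 100 of 100 splits gave as many, as any split gives at least 0, so the splits say nothing about chance there (highest other counts 2, 2 and 3).

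The glycolysis and hypoxia genes took a larger share of reads in co-culture in both lines. Depth alone is argued against by the size of the difference at like depth. This compared NSC34 libraries of 2000 to 5100 reads (4 per group, on average 3737 and 3785 reads). Their share was 0.491 ± 0.160% in controls and 1.03 ± 0.136% in co-culture, a difference of 0.537 of the 0.684 percentage points over all libraries. The sign of that difference was fixed beforehand, since all co-cultured shares lay above all controls, but its size was not. Carry-over between the lines is argued against as well: contractile reads allow at most 0.661% of C2C12 RNA in co-cultured NSC34 where 115% would be needed, and the neuronal share of C2C12 reads changed by -0.00373 points. Co-culture acting on the cells stays open: 9 of 9 members with 10 or more reads in both lines had a higher pooled share in both, which restates the pattern and does not tell its causes apart. It cannot be told apart from any other difference in culture or RNA handling between the groups, which the labels do not describe.

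Ribosomal protein and respiratory chain genes passed as lists in co-cultured C2C12 with the preset correlation but not with an estimated one (camera adjusted p = 0.289 and 0.267), with 0 of 58 and 0 of 23 members past the edgeR threshold, and fold changes were lower in longer transcripts (Spearman's rho -0.28 across 2560 genes, -0.34 in the deviation of co-culture 1 and 0.27 in that of control 3). With the length trend removed per library, the limma-voom median of the ribosomal list went from 0.07 to 0.0086 (camera adjusted p = 0.788), so a difference in fragment length between libraries may account for it. For the respiratory chain the median went from 0.12 to 0.0820 (adjusted p = 0.0768), and the trend cannot be told apart from a change in these genes, since most of the median was left. For the glycolysis, cholesterol, contractile and matrix lists the trend is argued against as the whole cause: their largest adjusted p with it removed and an estimated correlation was 0.0284. Of the 37 single C2C12 genes past the edgeR threshold, 24 still passed with the trend removed, and all 37 kept their direction. For those that no longer passed, the trend cannot be told apart from a change in the gene. A biological change in RNA length or stability in co-culture was not tested.

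Repeat-like gene models related to Gm10718 (11 genes with itself, at 80% identity or more) took 1.06 ± 0.609% of C2C12 control reads and 0.411 ± 0.232% of co-cultured reads (n = 6, exact p = 0.0411), and 0.942 ± 0.765% and 0.216 ± 0.196% in NSC34 (n = 6, exact p = 0.0238). Unspliced RNA or genomic DNA in the controls is possibly a source, but retained-intron transcripts changed by -0.325 points in C2C12 (exact p = 0.121) and by -0.602 in NSC34 (exact p = 0.647), in its direction yet short of the threshold. Without the transcripts of Elp6, Noct, Sirt5, Wdr31 and Sgip1, which share sequence with other genes, the changes were smaller. They were -0.132 points in C2C12 (exact p = 0.268) and -0.383 in NSC34 (exact p = 0.58). Among NSC34 libraries of 2000 to 5100 reads (4 per group) the means were 0.693 ± 0.515% and 0.157 ± 0.133%, a difference of -0.536 points against -0.726 over all libraries, and the shares overlapped (lowest control minus highest co-cultured share -0.106 points, exact p = 0.0857), so depth stays open. Co-culture acting on the cells also stays open: the smaller difference of the 2 lines was -0.653 points, in C2C12, which restates the pattern, and the same groups carry any difference in RNA handling.

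A library far from the others of its group was found in 8 of 86 groups of 6, where chance gives about 1 in 20 (4.3 groups). C2C12 control 2 had 658075 reads, against 121154 to 225344 in the other controls. The same library had the lowest Lrp4 level, 433 CPM, against 655 to 739 in the others. Rapsn was at 160.5 CPM in C2C12 co-culture 1, against 67.0 to 95.2. Chrnd was at 167 CPM in C2C12 co-culture 3, against 88.7 to 116. Actb was at 2699 CPM in C2C12 co-culture 6, against 2187 to 2360. NSC34 co-culture 2 had 30314 reads, against 2807 to 9554. NSC34 control 1, with 88 reads, had a respiratory chain share of 0%, against 1.22 to 1.74%. Rps23 was at 6533 CPM in NSC34 co-culture 6, against 17586 to 22732.

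The lines differed in the co-culture effect on 2 of 13 list totals by edgeR's interaction test. For cell cycle genes the NSC34 effect exceeded the C2C12 effect by 1.0 on the log2 scale (adjusted p = 0.000594), from 55 control and 304 co-cultured reads in NSC34, and by 0.99 without 4 control libraries, C2C12 controls 1 and 4 and NSC34 controls 1 and 6 (edgeR adjusted p = 0.00271). For glycolysis and hypoxia it exceeded it by 0.77 (edgeR adjusted p = 0.00944), while the exact permutation test gave an adjusted p = 0.355.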

How the results depend on the processing

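The length and GC corrections, the sets without 2 control libraries, without repeat-like genes or with 10 reads in total, and all tests of read shares were chosen after seeing the data. All 25 named C2C12 genes past the threshold kept their direction in each setting run. Of 1566 settings of 87 named C2C12 genes, 1392 kept direction and side of the threshold, 112 no longer passed (5 of them without an adjusted p from DESeq2), 29 newly passed and 33 changed sign, in 10 genes that never passed; of 238 settings of 14 NSC34 genes, 235 were kept and 3 changed sign. The 37 C2C12 genes became 58 with library totals (23 higher, 35 lower, against 21 and 16), 67 with DESeq2 (28 of the 37 among them, while 7 got no adjusted p and 2 did not pass), 106 with no filter (30 of the 37), 59 without repeat-like genes (35), 10 without control libraries 1 and 4 (9), and 11 to 74 with 1 library left out. The other counts follow, with those of the 37 still passing in brackets. They were 39 with RLE (37), 33 with limma-voom and quality weights (27), 44 with a mean of 10 (37) and 38 without mitochondrial genes (37). With the length trend removed the count was 31 (24), and with the GC trend removed 45 (28). The cause of these shifts was not tested. The 6 C2C12 lists were 4 with an estimated correlation or the length trend removed, 5 with fry, 6 with RLE or without control libraries 1 and 4, 7 with a mean of 10 or the GC trend removed, and 5 to 7 with 1 library left out. The list gained was cell cycle with fry, a mean of 10 or the replicate block, and mitochondrially encoded genes with the GC trend removed (median 0.22, camera adjusted p = 0.000605). Adjusted p over these settings and the replicate block (8 in all, each library left out apart) reached 0.0325 for the glycolysis and contractile lists, 0.0233 for the cholesterol and matrix lists, 0.267 for the respiratory chain and 0.788 for ribosomal proteins. The replicate block gave 26 C2C12 genes (20 of the 37), 7 C2C12 lists, 0 NSC34 genes and lists, and 0 genes that differ between lines; lists with a changed share went from 4 to 0 in C2C12 and from 1 to 0 in NSC34, since permuting within 6 numbers cannot give an exact p under 0.0312. The correlations gave no clear sign of pairing by number within a line. In each line 1 of 6 same-number correlations exceeded 0.1 (-0.05 to 0.10 and -0.23 to 0.32), and 1 of 6 libraries matched best with its own number. They cannot exclude pairing, and in NSC34 they rest on 49 genes. Co-cultured C2C12 and NSC34 libraries of the same number were not compared, and the tests between the lines treat them as independent. In NSC34, 10 reads in total gave 7 genes and 6 without control library 1. With 1 library left out 0 to 1 passed, and all other settings gave 0. Lists with a changed share were 0 without control libraries 1 and 6, where 1 list alone could not pass even at the smallest possible exact p. They were 2 with the 10 most counted genes left out, and 0 to 2 with 1 library left out. DESeq2 gave 2 genes that differ between lines. These uncalled log2 values changed sign: Jun (-0.003) was 0.0039 with RLE, 0.00039 with a mean of 10, 0.0022 with the replicate block and 0.074 with the length trend removed, Vamp2 -0.012 and Aen 0.0078 with quality weights, and Klf6 0.0039 with the length trend removed. With 1 library left out, Jun ranged from -0.14 to 0.11, Vamp2 from -0.076 to 0.24, Aen from -0.25 to 0.11, Ccng1 from -0.26 to 0.011, Lrp4 from -0.019 to 0.18, Rapsn from -0.31 to 0.11, Dok7 from -0.058 to 0.17, Hes1 from -0.033 to 0.25, Xaf1 from -0.051 to 0.093, and in NSC34 Cox6c from -0.25 to 0.090 and mt-Nd1 from -0.47 to 0.031. The test direction of lists that had not passed turned for the apolipoprotein list (median -0.038 with a mean of 10, 0.0083 with the length trend removed, -0.075 without control libraries 1 and 4, -0.21 to -1.86e-05 with 1 library left out), the mitochondrially encoded genes (-0.056 with the length trend removed, -0.043 to 0.092 with 1 left out; in NSC34 -0.39 to 0.025), the receptor apparatus (-0.022 to 0.16) and NSC34 ribosomal proteins (-0.10 to 0.077), and the cause was not tested. No C2C12 library was under 0.2 of the median depth, so that setting gave no value there. Depth limits NSC34, where 49 genes had enough reads to be tested. In the simulation, which drew its changed genes from those tested, 1 of 3 changed 4-fold still passed the filter.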

Other observations

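The genes in this part were chosen after their values were seen, from those past the planned edgeR threshold in C2C12 that the rule for named genes had left out. They are single genes, not a tested group (log2 fold changes, n = 6 per group). Pgam2, the muscle form of phosphoglycerate mutase, rose from 118 ± 28.0 to 198 ± 24.2 CPM (SD), by 0.67 (adjusted p = 0.0349 in edgeR). Ankrd2, an ankyrin-repeat protein of the sarcomere, rose by 0.69 (edgeR adjusted p = 0.0335). Vamp5, a vesicle protein of muscle, rose by 0.39 (edgeR adjusted p = 0.016), with all 6 co-cultured libraries above all controls. Cox8a, the widely expressed partner form of Cox8b, rose by 0.38 (edgeR adjusted p = 0.0347), and Map1lc3a, a protein of autophagosome membranes, by 0.49 (edgeR adjusted p = 0.0349). Brip1, a DNA helicase of repair, rose by 0.91 from 49.7 ± 13.9 to 88.0 ± 17.0 CPM (edgeR adjusted p = 0.0457). With 1 library left out, Vamp5 passed in 10 of 12 cases, Ankrd2, Cox8a and Map1lc3a in 5, and Pgam2 and Brip1 in 3. Over the 12 other settings Vamp5 passed in 12, Ankrd2, Cox8a and Map1lc3a in 9, Brip1 in 8 and Pgam2 in 7.

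Among the lower genes were Mbnl2, a muscleblind-like splicing regulator, which fell by 0.98 on the log2 scale (edgeR adjusted p = 0.0349), and Cald1 (caldesmon, an actin-binding protein), which fell by 0.53 (edgeR adjusted p = 0.0415). Ptma (prothymosin alpha), a nuclear protein of growing cells, fell by 0.42 (edgeR adjusted p = 0.0349). All 6 co-cultured libraries lay below the control median in these 3 genes (Mbnl2, Cald1, Ptma). With 1 library left out, Mbnl2 passed in 4 of the 10 cases in which it was tested, and Cald1 and Ptma in 3 of 12. Over the 12 other settings Ptma passed in 8 (largest adjusted p = 0.305, by any of edgeR, DESeq2 and limma), and Mbnl2 and Cald1 in 6. DESeq2 gave no adjusted p for Brip1 and Mbnl2. Reads on the 10 most counted genes made up 10.5 to 11.1% of each C2C12 library and 13.6 to 29.5% of each NSC34 library, the highest in the control library of 88 reads.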
